A study of Drosophila melanogaster with 2 samples.

How the data were processed

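The samples were 1 dBigH1 ChIP library and 1 input library from w1118 Drosophila melanogaster embryos collected 0 to 2 h after fertilization. Per the labels' protocols, libraries were made from 3.5 ng of DNA, size selected to 300 to 350 bp, amplified by 18 cycles of PCR and sequenced as single reads of 50 nt on a HiSeq2000. The submitters' processing notes name CASAVA 1.9, Bowtie2, FastQC 0.10, R 2.15 and the genome build dm3, without saying what each was used for. The gene annotation version, read filters, treatment of duplicate reads and of reads in overlapping genes, and the counting tool are not given in the sources used here. Of the 15627 genes, 6566 (42%) overlap another gene, so reads there cannot be assigned to either gene from these values.

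Per the file headers, the authors deposited 1 table with a log2 RPKM value per gene for each library and a score named as a MAnorm log2 fold change. From the values, the deposited log2 columns were log2(RPKM + 1): with 1 subtracted after undoing the log, 100% of values were a whole number of reads divided by gene width, within a tolerance of 1e-05 reads, against 0% when 0 or 0.5 was subtracted. This gave each gene's reads and the total by which each library had been scaled, 8803832 for the ChIP and 6272887 for the input. No gene was at 0, and the lowest value in each library was 1 read. Whether genes with 0 reads were left out before deposit is not given in the sources used here. Gene width in the deposited table was end minus start plus 1, so introns were included.

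The deposited score was not used as a log2 fold change, although the plan made before the data were examined gave it first place. Over all genes it had an SD of 1.00, and its slope on the log2 ratio ran from 1.80 to 3.40 over 20 bins of signal, as for a score divided by a local spread. Its Spearman rho with the log2 ratio was 0.991. The plan's fallback was therefore used: log2((ChIP RPKM + 1)/(input RPKM + 1)), with no further normalization between libraries. Adding 1 RPKM understates the ratio of genes with low signal. The score was kept as an alternative.

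Each gene's 95% interval is the exact Clopper-Pearson interval of the ChIP share of its reads, put on the same log2 scale. It covers counting error only. Intervals of pooled reads were computed in the same way, without the added 1 RPKM. The interval of a median is the binomial interval from the ordered values and describes the spread of genes. To see what counting alone would give, 200 tables were simulated in which each gene's reads were split between the libraries by their share of all reads. The counts under other pseudocounts and filters were set against these tables after the data were seen. Enriched and depleted genes were those with a log2 ratio of at least 1 or at most -1 and an input RPKM of at least 0.5 times its median. No test was run between the groups, since each had 1 library.

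Before the data were examined, 37 gene lists were fixed, of which 35 had at least 5 measured members. The list of linker histones had 1 (CG3509), and 1 list had none. Some genes are in more than 1 list. The median of each list and arm was set against 10000 random lists drawn with replacement within 10 bins of mean log2 RPKM, and called low or high at 2.5% in either direction. This describes these libraries and is not a test of the groups. Genes were matched by the symbols in the deposited table and by current symbols from a RefSeq table of the Release 6 assembly, through Entrez numbers (13076 genes matched). That table was used for names only, and coordinates are those of dm3 in the deposited table. A planned split by position within genes was left out because the table holds whole genes.

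The genes named are CG3509 and His1, the 10 lowest and 10 highest genes with a symbol, a width of at least 500 bp and the filter on input, and in each list described the lowest and highest member and that nearest the median. For the protease, eggshell and other lists given only by their medians, no member is named, except Cp190 in the eggshell list. Alternatives were a pseudocount of 0, 0.1 or 5 RPKM, centring, a lowess correction (span 0.3) on mean log2 RPKM, other filters on input, other thresholds, other matching of random lists, the mean in place of the median, 1 value per symbol and the middle 50% of gene widths. The deposited score became an alternative once its values were seen. Alternatives chosen after the data were seen were genes of at least 500 bp, genes with at least 20 input reads, a background of named genes of at least 500 bp, and, for medians and arms, the filter on input at 0.5 times its median.

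Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The procedure was tested on simulated data with the real genes and depths. It recovered 100% of reads, which had been written with the same formula and at least 1 read per gene. Changed genes were drawn from those with at least 20 input reads, so genes with fewer were not tried. Of 100 raised 2-fold in the ChIP, 96% had an interval above 0, and of 100 lowered 2-fold, 94% had one below 0. Their median log2 ratios came out at 0.86 and -0.88, short of 2-fold. Computed without the added 1 RPKM, the intervals covered the true ratio of 96.2% of genes. The simulated reads followed the binomial split that the intervals assume, so duplicate reads and overlapping genes were not tried. Of 200 unchanged lists, 3% were called low.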

Results

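dBigH1 is the linker histone H1 variant that packages chromatin in the early Drosophila embryo and in the germ line. The study asked where along the genome it lies in embryos collected 0 to 2 h after fertilization from the w1118 stock, a laboratory strain with white eyes. Chromatin immunoprecipitated with an antibody against dBigH1 was sequenced as 1 library, and input DNA, prepared without an antibody, as 1 library. Whether both came from the same collection of embryos is not given in the sources used here. The table of gene values covered 15627 genes on the dm3 build. Each value is for a whole gene, introns included, from its start to its end. The reads per gene summed to 5206548 for the ChIP and 3696767 for the input, which was 59.1% and 58.9% of the 8803832 and 6272887 reads by which the values had been scaled. The median gene had 98 ChIP and 74 input reads, and 752 and 979 genes had under 10 reads. Neither group had a replicate, so no difference below has a replicate check and no p-value is given. All 95% intervals of single genes and of pooled reads cover counting error only, and reads copied by PCR are not independent molecules.

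Across the genome, most genes had a scaled dBigH1 ChIP signal close to their scaled input. Each library was scaled to its own total reads, so a typical ratio near 0 does not give the overall amount of dBigH1 over genes. The median log2 ratio of ChIP to input was -0.04, with quartiles of -0.23 and 0.14. The central 90% of genes lay between -0.60 and 0.48. Median RPKM (reads scaled by gene width and library depth) was 6.38 in the ChIP and 6.51 in the input. The genes differed from each other by more than read counting gives where they were deeply covered. Among the 2605 genes with the most input reads (287 or more), the SD of the log2 ratio was 0.17, against 0.07 from counting alone. Among the 2605 with the fewest (26 or fewer), it was 0.63 against 0.61, so gene differences were barely detectable there. The interval of 1498 genes (9.59%) lay below the median of all genes and that of 1649 genes (10.6%) above it. In simulated data, 3.82% of the 15427 unchanged genes had an interval that missed their true ratio on either side. The sign of the genome-wide median depended on the scaling, and values below are best read relative to it.

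**Figure D1:**
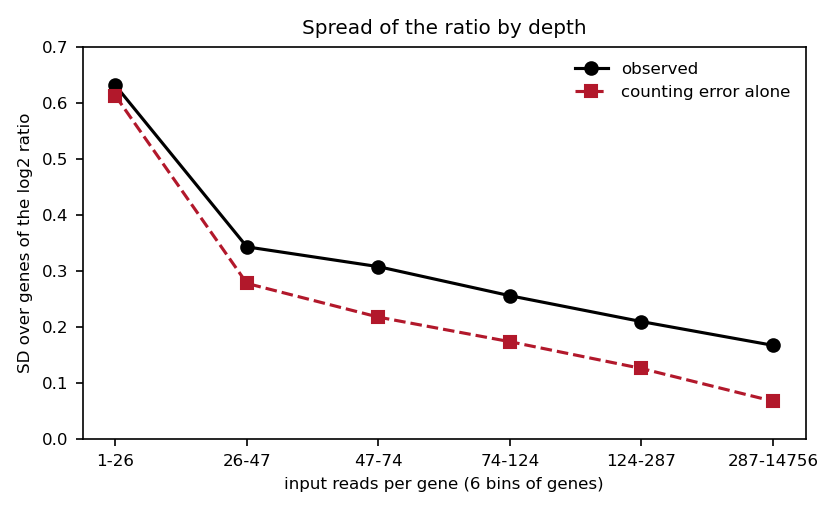
SD over genes of the log2 ratio of ChIP to input (vertical axis) in 6 bins of genes by input reads per gene (horizontal axis), as observed (black circles) and as read counting alone would give (red squares). The observed SD fell from 0.63 to 0.17 with depth, and the SD from counting from 0.61 to 0.07.

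Genes with 2-fold more or less dBigH1 ChIP than input were few, and most of the 10 at each end were short genes. The lowest ratios among genes of at least 500 bp with a symbol were those of CG7294 (-1.69, interval -2.48 to -0.71, from 5 ChIP and 19 input reads), the meiotic spindle gene mei-38 (-1.31), the ribosomal protein gene RpS24 (-1.25, interval -1.81 to -0.69) and the glycosyltransferase gene brn (-1.22). GstE5 (-1.16), a glutathione S-transferase gene, Vha14-1 (-1.15), which codes for a subunit of the vacuolar proton pump, CG17982 (-1.15), the Notch target m4 (-1.14), noe (-1.13) and CG15480 (-1.13) followed. The highest ratio belonged to the seminal fluid protein gene Sfp24Ba (1.39, interval 0.69 to 2.10, from 67 ChIP and 16 input reads). Next came CG33689 (1.36), CG42655 (1.17), the odorant-binding protein gene Obp56h (1.09), the ecdysone-induced gene Eig71Ek (1.04) and the stress-induced gene TotC (0.99). CheB74a (0.94), the gustatory receptor gene Gr22b (0.93), CG17380 (0.93) and CG6475 (0.93) completed the 10. All 20 intervals excluded the median of all genes. The genes were ranked by the same reads, so their intervals would tend to exclude it in any case. None of the 10 highest genes had input RPKM of at least its median, and without a filter on input 5 of them were among the 10 highest. Of the 100 lowest genes 25 lay on the X chromosome, as did 3 of the 100 highest and 1939 of the 12712 genes ranked.

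RpS24 lies at 2R 18528031 to 18528923 and had 3.69 RPKM in the ChIP and 10.2 in the input. Sfp24Ba lies at 2L 3667977 to 3668551 and had 13.2 and 4.44 RPKM. Among 15251 genes with input RPKM of at least 3.26, 66 had a log2 ratio of at least 1 and 183 of at most -1. Counting error alone gave 62.2 enriched genes on average (41 to 86 in 200 simulated tables) and 97.5 depleted genes (73 to 129), so the enriched genes did not outnumber those of counting error while the depleted genes did. Restricted to 13698 genes of at least 500 bp, a restriction chosen after the data were seen, both counts exceeded those of counting error. There were 6 enriched genes against 1.41 from counting (0 to 4) and 26 depleted genes against 2.54 (0 to 7). With no pseudocount the counts were 103 and 285 (95.7 and 138 from counting), with one of 5 RPKM 17 and 59 (17.1 and 30.6), and among genes with input RPKM of at least its median the enriched count was 17 (15). Without the filter on input it was 123 (127 from counting), and on the authors' deposited score, which is not a log2 ratio, a value of 1 or more was reached by 1692 genes and -1 or less by 1925.

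By chromosome, dBigH1 ChIP over input was low on the X and high over genes of heterochromatic scaffolds and of scaffolds with no assigned chromosome. The 2382 genes of the X had a median log2 ratio of -0.14 (interval of the median -0.15 to -0.12), against -0.03 over the 12900 genes of the arms 2L, 2R, 3L and 3R, a difference of -0.11. On the X, 378 genes had an interval below the median of all genes and 116 above it. The small, largely heterochromatic chromosome 4 had a median of 0.05 over 93 genes (0.02 to 0.07), with 28 genes above and 2 below by their intervals. The 88 genes on the heterochromatic scaffolds of chromosomes 2, 3 and X had a median of 0.20 (0.15 to 0.22), which was 0.22 above the autosomal arms. By interval, 41 of them lay above the median of all genes and 0 below.

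Among the heterochromatic scaffolds, medians were 0.25 on 3RHet (20 genes), 0.20 on 3LHet (23 genes), 0.17 on 2LHet (6 genes), 0.15 on 2RHet (26 genes) and 0.08 on XHet (13 genes). The 149 genes on scaffolds with no assigned chromosome (U) had a median of 0.27 (0.23 to 0.34), and 123 of them exceeded the median of all genes. The 14 genes of YHet had a median of 0.04 (-0.29 to 0.20), from low RPKM in both libraries (2.02 and 1.79). The major autosomal arms differed little, from -0.04 on 2R to -0.01 on 2L. None of 10000 random sets of genes of the same size, matched on mean log2 RPKM, had a median as low as the X or as high as U or as the pooled 88 genes of the heterochromatic scaffolds. Singly, XHet (760 random sets as high, interval of the median -0.12 to 0.48) and 2LHet (519) did not stand out. For chromosome 4, 24 random sets had a median as high. Among the major autosomal arms, 0 random sets were as high as 2L, although it lay only 0.02 above those arms pooled. For 3L 135 sets were as high, and for the pooled arms 83. The arms 2R (1343 as low) and 3R (4010 as high) did not stand out. With this many genes, the X included, random sets single out small differences too, so their counts do not give the size of a difference. The X difference was -0.19 among genes with input RPKM of at least its median and -0.06 with a pseudocount of 5 RPKM. With that pseudocount the difference of the heterochromatic scaffolds was 0.15. At the same filter and pseudocount the U difference of 0.29 from the autosomal arms was 0.18 and 0.17, and that of chromosome 4, 0.08, was 0.16 and 0.05.

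**Figure D2:**
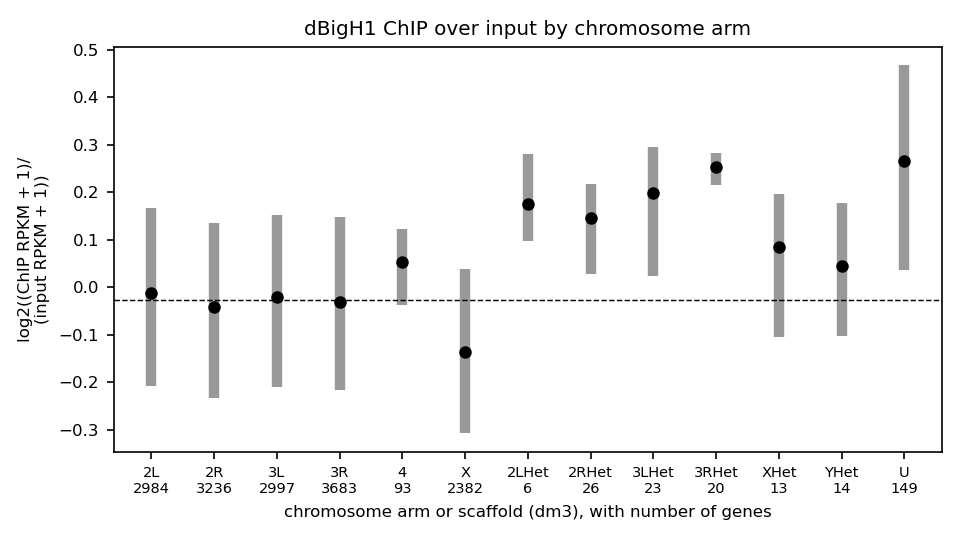
Median (black point) and interquartile range (grey bar) of the log2 ratio of ChIP to input, with 1 RPKM added to both (vertical axis), for the genes of each chromosome arm or scaffold of dm3 (horizontal axis, with the number of genes). The X median was -0.14, the dashed line marks the autosomal arms at -0.03, and the 3RHet median was 0.25.

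For the gene lists, a list was called low or high where at most 250 of 10000 random lists of the same size and matched mean log2 RPKM had a median as low or as high. Of the 35 lists with at least 5 measured members, 13 were low and 9 were high, against 0.875 expected in each direction by chance. Genes that act in the first hours of the embryo, the cell cycle and protein synthesis made up most of the low lists. Genes of chemosensory organs, male accessory glands, detoxification and heterochromatin made up most of the high lists. Members of a list are often neighbours or copies of each other, so the random lists treat them as more independent than they are.

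The pair-rule genes, which divide the embryo into segments, had a median log2 ratio of -0.51 (-0.59 to -0.17), and all 9 members lay below the median of all genes, 6 of them by their intervals. The lowest was eve (-0.62, interval -1.12 to -0.12, from 41 ChIP and 50 input reads), the middle one was slp1 (-0.51) and the highest was prd (-0.06, interval -0.39 to 0.27). The 10 early zygotic genes of cellularization and X counting had a median of -0.45 (-0.84 to 0.02), with 5 members below by their intervals. They ranged from Z600 (-0.87), an inhibitor of mitosis in the early embryo, through slam (-0.48, interval -0.71 to -0.24), a gene needed for furrow formation, to nullo (0.27, interval -0.43 to 0.97). The 23 zygotic dorsoventral genes had a median of -0.24 (-0.37 to -0.13), with 20 members below the median of all genes and 11 by their intervals. Their extremes were brk (-0.59, interval -0.89 to -0.29), a repressor of Dpp target genes, and zen2 (0.22, interval -0.27 to 0.73), and rho (-0.24) lay nearest their median.

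The gap, segment polarity and Hox lists were not called against lists of matched signal, although the gap and segment polarity lists were low against lists matched on gene width (112 and 110 of 10000 as low). The 14 gap and terminal genes had a median of -0.19 (369 of 10000 random lists as low), from tll (-0.59, interval -0.92 to -0.25) to croc (0.15), with oc (-0.27) nearest the median. The 10 segment polarity genes had a median of -0.16 (701 random lists as low), from the Hedgehog receptor gene ptc (-0.51, interval -0.63 to -0.39, from 817 ChIP and 871 input reads) to gsb-n (0.05), with en at -0.17. The 8 Hox genes, which are long and well covered, had a median of -0.08 (2998 random lists as low). Among them Ubx was lowest (-0.14, interval -0.19 to -0.08), Abd-B lay at -0.09 and pb was highest (0.05, interval -0.04 to 0.13). The 39 maternal effect genes, which are transcribed in the ovary, had a median of -0.02 (-0.11 to 0.07), close to that of all genes. They ranged from gnu (-0.68, interval -1.17 to -0.19), a regulator of the first nuclear divisions, to ndl (0.23, interval 0.07 to 0.40), with gd at -0.02.

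The 25 cell cycle and replication genes had a median of -0.37 (-0.45 to -0.20), and 22 lay below the median of all genes, 15 by their intervals. CycB3 was lowest (-0.74, interval -1.10 to -0.39, from 79 ChIP and 105 input reads), CycA lay at the median (-0.37, interval -0.55 to -0.19) and cdc2, the kinase that drives mitosis, was highest (0.27, interval -0.12 to 0.66). The 25 zygotic genome activators and chromatin factors had a median of -0.24 (-0.34 to -0.06). Their lowest member was the insulator gene BEAF-32 (-0.47, interval -0.82 to -0.12), grh (-0.24, interval -0.31 to -0.16) lay at the median, and Trl, which codes for the GAGA factor, was highest (0.11, interval -0.02 to 0.23).

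Genes of protein synthesis and turnover were low in every list. The 88 cytoplasmic ribosomal protein genes had a median of -0.30 (-0.35 to -0.20), with 76 below the median of all genes, and ranged from RpS24 through RpL30 (-0.31) to RpL37b (0.48, interval -0.44 to 1.42). The 72 mitochondrial ribosomal protein genes had a median of -0.33 (-0.40 to -0.25), from mRpS22 (-1.04, interval -1.53 to -0.54) through mRpL39 (-0.33) to mRpL49 (0.52). The 51 translation factor genes had a median of -0.21 and ranged from ligatin (-0.67) through eIF4E-6 (-0.21) to CG4810 (0.42). The 49 proteasome genes had a median of -0.18, from Prosbeta3 (-0.95, interval -1.52 to -0.37) through Rpt3R (-0.18) to Rpn12 (0.81, interval 0.22 to 1.40). The 16 heat shock genes had a median of -0.23 with 15 below the median of all genes, but 0 by their own intervals. The early zygotic, dorsoventral, chromatin factor and translation factor lists were not low among genes with input RPKM of at least its median, and the heat shock call was lost under 7 of 15 alternatives.

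Chemosensory receptor genes, which are expressed in sensory neurons of larvae and adults, were high as 3 separate lists. The 60 ionotropic receptor genes had a median of 0.19 (0.12 to 0.26), with 52 above the median of all genes, 20 by their intervals and 0 below by theirs. They ranged from Ir76a (-0.26, interval -0.50 to -0.02) through Ir94h (0.19) to Ir7a (0.61, interval 0.15 to 1.07). The 59 odorant receptor genes had a median of 0.18 (0.06 to 0.24), from Or2a (-0.43) through Or67b (0.18) to Or94a (0.76, interval 0.27 to 1.26). The 61 gustatory receptor genes had a median of 0.15 (0.08 to 0.28), from Gr59a (-0.35) through Gr39b (0.15) to Gr22b (0.93, interval 0.40 to 1.46).

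The 50 accessory gland genes, whose products are transferred in seminal fluid, had a median of 0.26 (0.15 to 0.43), from Acp29AB (-0.46) through Acp36DE (0.25) to Sfp24Ba. The 85 cytochrome P450 genes had a median of 0.14 (0.06 to 0.19), from Cyp6t1 (-0.56) through Cyp9h1 (0.14) to Cyp6a8 (0.67, interval 0.26 to 1.08). The 17 genes in or beside pericentric heterochromatin had a median of 0.16 (0.05 to 0.20), and 12 of them lay above the median of all genes by their intervals. The ribosomal protein gene RpL38 was lowest there (-0.19, interval -0.92 to 0.55), scro lay at 0.16 (interval 0.08 to 0.23, from 3044 ChIP and 1919 input reads) and the splicing factor gene Spf45 was highest (0.46, interval 0.04 to 0.87). The 18 salivary glue and Eig71E genes had a median of 0.25 (-0.27 to 0.48) and ranged from Eig71Ea (-0.51) through Eig71Ee (0.19) to Eig71Ek. The odorant receptor list was not high among genes with input RPKM of at least its median. Its own median there was -0.0075, against -0.12 over all genes that passed this filter. The salivary glue list was not high there (median -0.29) and turned low among genes with at least 20 input reads (-0.24), and its pooled reads gave a log2 ratio of -0.06 (-0.19 to 0.07).

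Other lists of genes used late or in particular tissues were neither low nor high against lists of matched signal. Their medians were 0.09 for 21 muscle genes, 0.08 for 9 yolk and larval serum protein genes, 0.07 for 14 antimicrobial peptide genes, 0.06 for 9 Y-linked genes and 0.03 for 22 neuronal genes. The muscle list was high against lists matched on gene width (182 of 10000 as high) and against named genes of at least 500 bp. The lists of 123 cuticle protein genes (-0.02), 33 digestive protease genes (-0.02), 16 genes listed as eggshell genes (-0.03) and 28 testis genes (-0.07) had medians close to that of all genes (-0.04). The eggshell list also took in Cp190 (-0.09), the gene of a centrosomal protein and not of the eggshell, with 314 of the list's 941 ChIP reads.

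**Figure D3:**
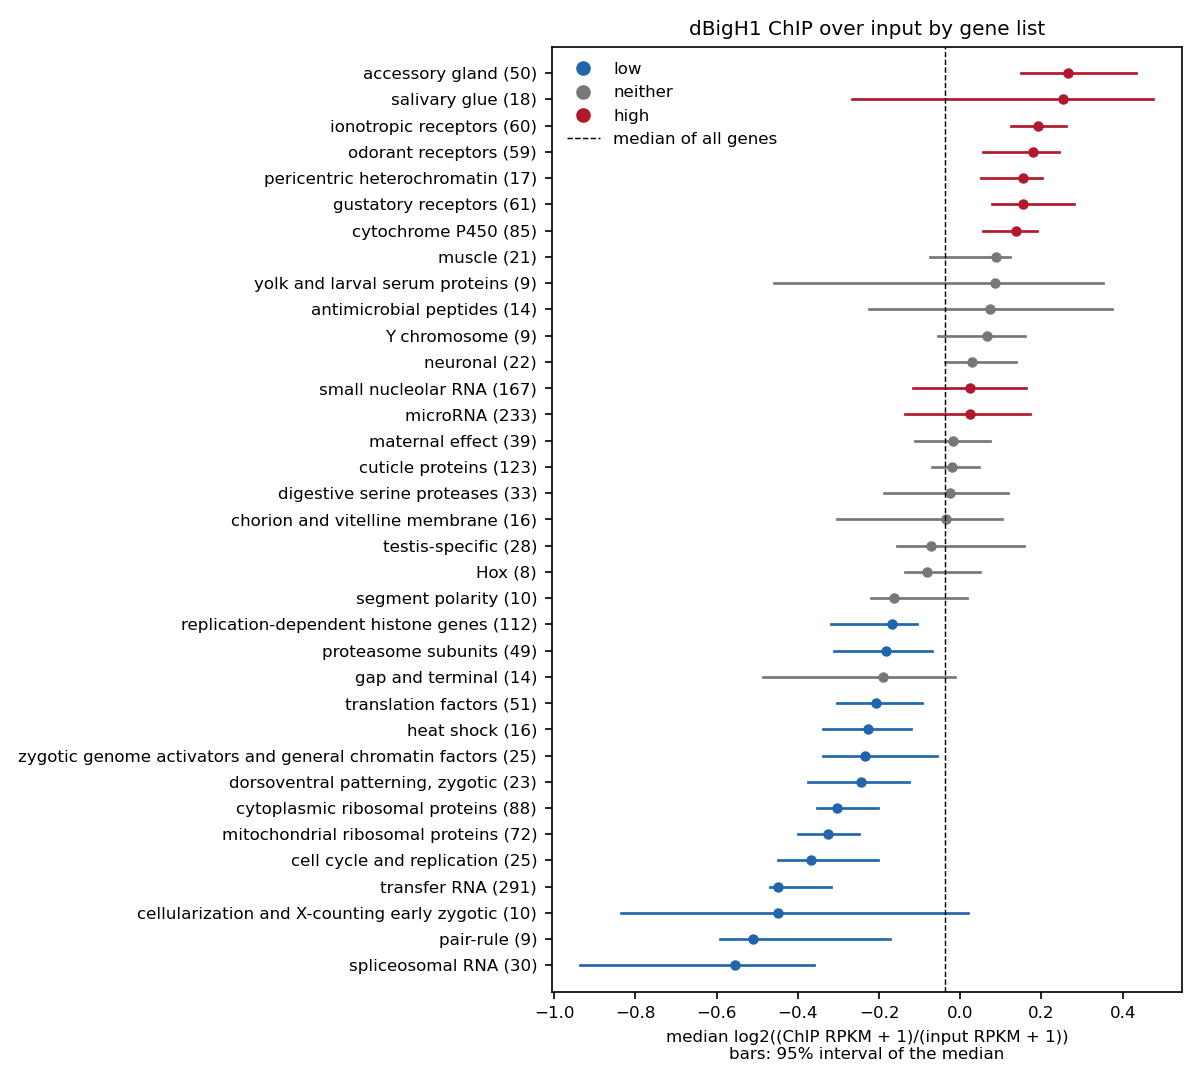
Median log2 ratio of ChIP to input, with 1 RPKM added to both (horizontal axis), of the 35 lists with at least 5 members (vertical axis, number of genes in parentheses), with the 95% interval of the median from the ordered values. Blue lists were low and red lists high against random lists of matched mean log2 RPKM, grey lists neither, and the dashed line is the median of all genes (-0.04).

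Genes of histones and small RNAs gave mixed values from few reads. The 112 histone genes of the replication-dependent cluster had a median of -0.17 (-0.32 to -0.11), a low call that was lost when the random lists were matched on input RPKM or when copies were averaged. The 23 copies of His1 among them, the somatic linker histone gene, had 1542 ChIP and 1002 input reads together. Their pooled log2 ratio was 0.13 (0.02 to 0.25), so they went the other way from the median of the whole list. The gene of dBigH1 itself, CG3509 (FBgn0038252, 3R 10489165 to 10490544), had 117 ChIP and 81 input reads and a log2 ratio of 0.04 (-0.34 to 0.42). Genes of transfer RNA (291 genes, -0.45) and of small nuclear RNA (30 genes, -0.56) were low, with a median of 5 and 8.5 ChIP reads per gene. Under 5 of their members had at least 20 input reads or had both a symbol and a width of at least 500 bp, so neither call could be repeated there. Genes of microRNA (233 genes) and small nucleolar RNA (167 genes) had medians of 0.02, which were high against random lists of matched signal but not against lists matched on gene width. The microRNA list turned low among genes with input RPKM of at least its median (-0.20). Among genes with input RPKM of at least 0.5 times its median, these medians were -0.067 and -0.027. Near-identical copies of histone and transfer RNA genes share reads, and how these were assigned is not given in the sources used here.

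Across all genes, ChIP and input levels were moderately related, and short genes were not much lower or higher than long ones. Pearson's r of log2 RPKM was 0.58 and Spearman's rho 0.55 across 15627 genes, which are not independent replicates. Over the 4110 genes of at least 4000 bp, r was 0.72 and rho 0.67. The log2 ratio had a Spearman rho of 0.02 with gene width. In the 4 quartiles of width, from the shortest to the longest genes, its median was -0.01, -0.07, -0.08 and -0.0044, while its SD fell from 0.56 to 0.18. Among genes with input RPKM of at least its median, rho with width was 0.17 and Pearson's r of ChIP with input was 0.37.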

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

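Genes of at least 500 bp, genes with at least 20 input reads, named genes of at least 500 bp as background, and the filter at 0.5 times the median input outside the counts of enriched genes were settings chosen after the results were seen. The deposited score, which the plan had put first as a log2 ratio, was made an alternative after its values were seen. No paired analysis was possible because each group has 1 library and no result comes from a test. The planned ratio without the authors' normalization is the one reported, as is the absence of a filter for medians, arms, lists and correlations. Depth limits what single genes can show: counting gives an SD of 0.61 among genes with 26 or fewer input reads.

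The genome-wide median (-0.04) became positive after a lowess correction (0.0035) and on the deposited score (0.016), and 0 by construction when centred. It was -0.045 without a pseudocount, -0.025 with one of 5 RPKM and -0.12 among genes with input RPKM of at least its median. That filter selects on the denominator, which by itself lowers the ratio. There the medians of odorant receptor, salivary glue, microRNA and small nucleolar RNA genes were negative (-0.0075, -0.29, -0.20 and -0.069), the number of high lists 5, the enriched genes 17, Pearson's r 0.37, Spearman's rho 0.31 and rho with width 0.17. With the filter at 0.5 times the median these correlations were 0.54, 0.53 and 0.046, and the microRNA and small nucleolar RNA medians -0.067 and -0.027. With at least 20 input reads the salivary glue and small nucleolar RNA medians were -0.24 and -0.069. These filters remove members, and the cause was not tested further.

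Enriched genes (66) numbered 103 without a pseudocount, 102 with 0.1, 17 with 5, 123 without a filter, 411 at a threshold of 0.58, 2 at a threshold of 2, 6 among genes of at least 500 bp and 1692 on the score. Depleted genes (183) numbered 285 without a pseudocount, 59 with 5, 826 at 0.58, 16 at 2, 26 among genes of at least 500 bp and 1925 on the score. The score is on a wider scale, which changes its counts by construction, and a larger pseudocount shrinks every ratio.

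The X minus autosome difference (-0.11) was -0.13 without a pseudocount, -0.13 with 0.1, -0.061 with 5, -0.072 after lowess, -0.19 with input of at least its median and -0.22 on the score. That of the heterochromatic scaffolds (0.22) was 0.26, 0.26 and 0.15 with pseudocounts of 0, 0.1 and 5, 0.26 with the higher input filter and 0.69 on the score. That of U (0.29) was 0.39, 0.38 and 0.17 with those pseudocounts, 0.18 with the higher filter, 0.37 in the middle 50% of widths and 0.71 on the score. That of chromosome 4 (0.08) was 0.16 with the higher filter and 0.26 on the score. The cause of the changes with filter and width was not tested. No arm difference changed direction.

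Of the 13 low and 9 high lists, 5 and 5 kept their call under all 15 alternatives. The low ones were the pair-rule, cell cycle, proteasome and both ribosomal protein lists. The high ones were the gustatory, ionotropic, accessory gland, cytochrome P450 and heterochromatin lists. The salivary glue list turned low with at least 20 input reads and the microRNA list with input of at least its median. Transfer and small nuclear RNA genes were low under all 13 alternatives that left at least 5 members. The eggshell, yolk, protease, Y-linked, microRNA and small nucleolar RNA lists also had too few members under some filters to give a value. Matched on gene width, the gap and segment polarity lists became low and the muscle list high, and the muscle list was also high against named genes of at least 500 bp. Centring adds 0.04 to every gene, which by construction turns the small negative medians of the maternal effect, cuticle, protease and eggshell lists positive. Of the 10 lowest and 10 highest genes, 5 and 8 were also among the 10 by the score, 10 and 5 without a filter, and 8 and 0 with input of at least its median. For single genes and list medians, 1097 values moved by less than the interval, 140 by more, and 8 values of called list medians changed sign.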

Other observations

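The grouping of genes into families by symbol, the comparison of neighbours and the tests of more input reads, first transcription in the embryo (both tests), the share of males (with its resampled intervals), lower signal of X-linked genes and chance order of genes were chosen after the results were seen. In the families, 67 groups of genes, 11 were low and 17 high against random lists matched on gene width. The groups share a stem of their symbols, except the Su(Ste) repeats, which were grouped by their description. A shared stem need not mean a family, as for l( (83 genes, median -0.17), 1 of the low groups. Low families outside the lists above included 25 genes of the Mediator complex, which links transcription factors to RNA polymerase II (MED, median -0.28, interval -0.58 to -0.18), 10 of the Integrator complex (IntS, -0.26, interval -0.38 to -0.12) and 15 nucleoporin genes (Nup, -0.20, interval -0.31 to -0.11). The 10 Rpn genes of the proteasome regulatory particle had a median of -0.38 (interval -0.50 to -0.0031), while the other proteasome families Pros (10 genes, -0.28, interval -0.69 to 0.05) and Prosbeta (10 genes, -0.018, interval -0.48 to 0.29) and the eIF family of translation factors (28 genes, -0.09, interval -0.25 to -0.05) were not called low.

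High families included 22 seminal fluid protein genes (Sfp, 0.36, interval 0.14 to 0.49), 16 UDP-glycosyltransferase genes (Ugt, 0.24, interval 0.03 to 0.39), 14 pickpocket sodium channel genes (ppk, 0.25, interval -0.10 to 0.36), 44 odorant-binding protein genes (Obp, 0.15, interval -0.05 to 0.32) and 19 dpr genes of neuronal surface proteins (dpr, 0.10, interval 0.01 to 0.19). The 40 Su(Ste) repeats, the source of RNAs that silence Stellate in testis, had a median of 0.32 (0.17 to 0.43) from 1284 ChIP and 704 input reads that near-identical copies share. Copies of a family often lie side by side, so its members are not independent.

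The early zygotic, pair-rule and cell cycle lists were low. Their 34 autosomal genes had a median ChIP RPKM of 5.53 (interval 4.85 to 5.97), below the 6.63 of all autosomal genes, so more input reads alone do not account for the ratio, although their input was also higher (7.70 against 6.77). Short width is argued against too: at most 5 of 10000 random lists matched on width had a median as low, and at most 2 in a separate draw. Whether genes first transcribed in the embryo carry less dBigH1 than genes transcribed in the ovary stays open. The 73 patterning genes lay -0.20 from 39 maternal effect genes, the direction this needs. The cell cycle list lay -0.36 from the 38 maternal effect genes outside it. Most of its genes were taken to be transcribed in the ovary, in which case first transcription in the embryo would not lower it. The cytoplasmic and mitochondrial ribosomal protein lists, which were not picked for embryonic transcription, were low as well (-0.30 and -0.33). The patterning and cell cycle differences restate the list medians that raised the question, and no values used here give transcript levels in the ovary. A difference in GC bias between the 2 libraries stays open, since 0 genes had a GC value in the files used.

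The X chromosome was low. The pseudocount is argued against, since the difference without one was -0.13, and lower signal of X-linked genes likewise, since within bins of mean log2 RPKM the difference was still -0.10 and negative in 9 of 10 bins. If ChIP and input came from separate collections of embryos, which the labels leave unsaid, and the ChIP embryos included more males, the Y would be higher: taking 50% males in the input, the X difference needs 61.3% in the ChIP and a Y difference of 0.29. This stays open, since the 16 Y-linked genes had a pooled difference of 0.092 (-0.0077 to 0.23 with genes resampled), below that amount, but the 40 Su(Ste) repeats, which come from the Y and are unplaced in dm3, had 0.36 (0.25 to 0.47), which is not particular to the Y, since 108 other genes on U had 0.26 (0.22 to 0.29), and the Y-linked genes and repeats together had 0.15 (0.08 to 0.29), with an upper bound at the amount needed. As a hypothesis, the X may carry less dBigH1 than autosomes, which ChIP and input from embryos of known sex, set against the GC content of each gene, would test.

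Neighbouring genes had similar ratios. Across 9141 pairs of adjacent, non-overlapping genes of at least 1000 bp, Pearson's r was 0.25, above all 1000 shuffled gene orders (at most 0.03). It was 0.18 for pairs at least 1000 bp apart, which argues against DNA fragments that reach into both genes. For pairs whose symbols share no stem it was 0.22, which argues against families with a shared stem as the whole cause. Relatives with unlike symbols can remain among these pairs, since CG6475, for one, is now named Ugt49B2. The correlation fell to 0.08 at 5 genes apart (median 37.0 kb) and 0.03 at 10 genes apart (85.1 kb). As a hypothesis, domains of chromatin with more or less dBigH1 could give this, and so could regional GC content; comparing neighbours of equal GC content in replicate libraries would tell these apart.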
